A study of Mus musculus with 52 samples.

How the data were processed

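RNA from the frontal cortex of 52 mice was sequenced, 1 library per animal. All mice carried APP transgenes, which drive amyloid plaque formation, and were homozygous for human APOE3 or human APOE4 in place of mouse Apoe. They are called APP/E3 and APP/E4. Males and females of both genotypes were fed normal chow (ND) or a Western high-fat diet (HFD) in which milk fat and corn oil gave 40% of calories, carbohydrate 42.6% and protein 16.8%, per the labels' protocols. The protocols give a mean age of 3.5 months at the start of the diet, 3 months of feeding and behavioural tests at a mean age of 14.7 months. How these ages relate is not stated, and the age of each animal is not given, so age was not used. Mice were perfused before dissection, RNA with an integrity number above 8 was used, and libraries were made with an Illumina mRNA kit, per the labels' protocols. Genotype, diet and sex were taken from the labels, which put each library in 1 of 8 groups. Replicate numbers within a group follow the deposit order and pair nothing.

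The authors deposited 1 table of raw read counts per gene for all 52 libraries, with no column of any other sample. Subread, featureCounts, limma and edgeR 3.14.0 and genome build mm9 are named in the submitters' processing notes, without their order or settings. The annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here, so counts of near-identical gene copies and of overlapping or antisense genes are uncertain. The same deposited table holds a log2 coefficient and an unadjusted p-value for each gene from the authors' own comparison of diets over all libraries, and a shorter deposited table repeats these for the genes with a p-value under 0.05. These columns were used only for a comparison with the fits made here. The table lists 15692 genes by gene ID and symbol. Spreadsheet software had turned 24 symbols into dates, and all 24 were restored through their gene IDs. Of the gene IDs, 15448 were found in a RefSeq gene table for the mouse assembly GRCm38.p6, which was used for names, gene types, chromosomes and the order of neighbouring genes only, since the counts were made on another build.

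Total counts ranged from 5.34 to 13.1 M per library except for 1 library of 39.4 M. At these depths 3 counts correspond to between 0.0762 and 0.561 CPM (counts scaled to a library total of 1 M) in a library, and values below that are not distinguished from 0. This floor covers counting error only. No pair of libraries within a group was a duplicate: over 146 pairs the chi-square per gene between their counts was 3.06 at the lowest, with a median of 12.0.

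Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 8 groups, which removed 497 genes and left 15195. Counts were scaled with TMM factors, and a robust quasi-likelihood model with 1 mean per group was fitted to all 52 libraries. The 12 contrasts were the effect of HFD against ND averaged over genotype and sex and within each of the 4 combinations of genotype and sex, the interaction of diet with genotype averaged over sex and within each sex, the interaction of diet with sex averaged over genotype and within APP/E4, APP/E4 against APP/E3, and female against male. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. CPM of groups, of pooled groups and of the sex check use total counts. Log2 values, list scores and the CPM that mark read classes and single libraries use TMM-scaled totals, and log2 CPM carry a prior count of 2. Errors of log2 differences are standard errors (SE) and errors of CPM are standard deviations (SD).

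For gene lists, 33 were written before the data were examined. They cover plaque-associated (DAM) and homeostatic microglia, the Tyrobp immune network, complement, interferon response, antigen presentation, reactive astrocytes, astrocyte identity, myelin, oligodendrocyte precursors, excitatory and inhibitory neurons, immediate early genes, endothelium, mural cells and meningeal fibroblasts, choroid plexus, blood, striatum, olfactory bulb, hippocampus and thalamus, cholesterol synthesis, lipid handling, fatty acid oxidation, glucocorticoid response, circadian clock, oxidative phosphorylation, cytosolic ribosome, protein folding, transcription and chromatin regulators, cell migration, Alzheimer risk genes, and X-linked and Y-linked genes used as a sex check. A list of the 4 engineered or matching loci was below the minimum of 5 genes and was not tested as a list. The remaining 32 lists were tested against all other genes with limma 3.58.1 camera at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which does not compare a list with other genes. A list was called at an adjusted p under 0.05 over the 32 lists of a contrast. The Tyrobp, transcription and migration lists were prompted by themes named in the series description, so their direction is not independent evidence. The mean log2 CPM of the 45 measured Tyrobp network genes was compared between diets by 2-sided exact permutation tests in the 4 combinations of genotype and sex, adjusted over these 4, and the means of the other lists were compared the same way. Each of these differences was also computed with single libraries left out.

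The genes named in the text follow a rule written before the data were examined. Where 5 or more genes were called, the rule takes the 10 highest and 10 lowest log2 differences among called genes with a mean log2 CPM of at least 1. Where fewer were called it takes the 5 genes of smallest p. From each list it takes up to 4 members of smallest p and up to 10 called members. It always takes Tyrobp, Trem2, Apoe, App, Prnp, Xist and Ddx3y. Predicted genes without a name were counted and not named. Genes outside this rule are said to be so, and some genes that it takes are not reported here.

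Libraries fell into classes on features other than their groups. They were clustered by Ward's method on the log2 CPM of 280 genes that RefSeq types as pseudogenes, and the tree was divided into 3 read classes. Library titles also differ: the titles of all females and some males end in a sex letter, and those of other males do not. The sex comparison was therefore repeated with read class as a term, within class 1 alone, and with read class and title style together. These fits with read class were chosen after the data were examined.

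Other settings chosen before the data were examined were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors in edgeR, no filter, a stricter filter (CPM of at least 1 in at least 5 libraries), 2 surrogate variables from sva 3.50.0, title style or animal number as a covariate, a fit on the contrast's own libraries, males with a sex letter alone, and leaving out each library in turn. Added after the data were examined were the read class fits, scores of the olfactory bulb, striatum and choroid plexus lists as covariates, and fits without doubted libraries. The same libraries were also regrouped at random 100 times per comparison. Before use, the fits were tested on simulated counts in which 50 genes each were changed 1.25-fold, 1.5-fold, 2-fold and 4-fold. All 4 sizes of change were in the same simulated set and were adjusted together. With so many changed genes the adjusted threshold is easier to pass, so these shares may overstate recovery where few genes change. For the averaged diet effect 193 genes were called, 10 of them unchanged, and for APP/E4 females 137, 11 of them unchanged. For the averaged diet effect over 15195 genes, 74% of 1.25-fold and 94% of 1.5-fold changes were recovered. For the diet effect in APP/E4 females these shares were 20% and 56%, with 84% of 2-fold changes recovered, and for the diet by genotype interaction in females 18% and 52%. For APP/E4 against APP/E3, 66% and 88% were recovered, and for female against male 60% and 96%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.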

Results

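Messenger RNA was measured in the frontal cortex of 52 mice that carried APP transgenes that drive amyloid plaque formation, together with human APOE3 or human APOE4. The design crossed APOE genotype with diet and sex. The APP/E3 mice comprised 6 ND males, 6 HFD males, 7 ND females and 8 HFD females, and the APP/E4 mice 6 ND males, 5 HFD males, 7 ND females and 7 HFD females. Each library held between 5.34 and 13.1 M counts, except APP/E3 ND male 5 with 39.4 M, and group medians lay between 8.05 and 10.2 M. Xist, transcribed from the inactive X chromosome, lay between 461 and 1126 CPM in the 29 females and between 0 and 1.89 CPM in the 23 males. The Y-linked gene Ddx3y lay between 59.0 and 170 CPM in males and at most at 0.772 CPM in females, so every library matched its labelled sex. The human APOE sequence is not separated from mouse Apoe in a table of mouse genes, so these counts do not check the genotype labels.

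Libraries differed in a way that their groups do not explain. In 11 female libraries the counts of Rps10, a ribosomal protein gene with many processed pseudogenes, lay between 17.8 and 25 TMM-scaled CPM, against 1.49 to 4.28 CPM in 33 other libraries of both sexes. Csl, a citrate synthase-like gene, lay between 0.0936 and 1.15 CPM in the same 11 libraries and between 10.7 and 18.2 CPM in the 33. Clustering on pseudogenes gave class 1 with these 33 libraries (18 female, 15 male), class 2 with the 11 females, and class 3 with 8 males whose titles lack a sex letter. Class 2 held 2 of 7 APP/E3 ND, 5 of 8 APP/E3 HFD, 2 of 7 APP/E4 ND and 2 of 7 APP/E4 HFD females. With class terms added to the 8 group means, edgeR called 3462 of 15195 genes for class 2 and 43 for class 3, each against class 1. With title style added as well, 271 genes were called for a title without a sex letter. The main fits carry neither term. For the leading genes and some lists of the comparison of the sexes, values within class 1 are given as well.

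**Figure D1:**
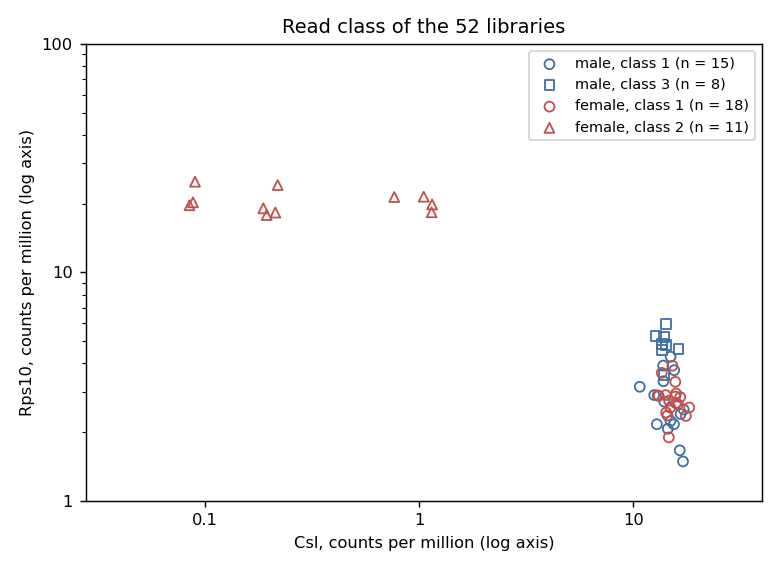
TMM-scaled CPM of Csl (x axis, log scale) against that of Rps10 (y axis, log scale) in the 52 libraries, 1 point per library, marked by sex and read class. The 11 class 2 libraries, all female, lie between 17.8 and 25 CPM of Rps10, above the 33 class 1 libraries of both sexes.

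The comparison of APP/E4 with APP/E3 mice, averaged over diet and sex, asked how the APOE allele shapes cortical expression in mice with amyloid. Serpina3n, a secreted serine protease inhibitor of reactive astrocytes, rose from 19.95 ± 6.67 CPM in APP/E3 (SD, n = 27) to 101 ± 28.4 CPM in APP/E4 (SD, n = 25), a log2 difference of 2.31 ± 0.12. Its neighbour Serpina3m was at 0.0588 ± 0.112 CPM in APP/E3, below the level of 3 counts, and at 4.09 ± 1.29 CPM in APP/E4. These paralogs can share reads, so the split between them is uncertain. Several genes of plaque-associated microglia rose. Clec7a, a phagocytic pattern receptor, went from 1.28 ± 0.62 to 3.36 ± 1.93 CPM, the integrin gene Itgax from 1.14 ± 0.45 to 2.83 ± 1.47 CPM, and the cystatin gene Cst7 from 2.13 ± 1.34 to 5.40 ± 3.52 CPM.

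Of 15195 genes tested, edgeR called 1032, 515 higher and 517 lower in APP/E4, with a median absolute log2 difference of 0.18 and 36 genes above 1. Of the plaque-associated microglia list, 25 of 29 genes were higher and 12 were called, all higher, and 18 were called higher and 2 lower when adjusted over the list alone. Besides Clec7a, Itgax and Cst7, these included Ccl6 (log2 difference 0.82 ± 0.11), Lilrb4a (1.0 ± 0.24), Ccl3 (0.89 ± 0.22), Lgals3bp, the lysosomal protease gene Ctsd (0.20 ± 0.04), Cd9 and Cd68. Camera called the list (adjusted p = 6.8e-10), but not with an estimated correlation (adjusted p = 0.0796), while fry gave an adjusted p of 3.6e-05. Of the Tyrobp immune network, 41 of 45 genes were higher and 10 were called, all higher, and adjusted over the list alone 18 were called higher and 1 lower. They included the perforin-like gene Mpeg1, at 56.6 ± 10.8 CPM in APP/E3 and 82.5 ± 19.9 CPM in APP/E4, the NADPH oxidase subunit Cybb (0.88 ± 0.16), Cd84, Itgb2 and Trem2, the microglial lipid receptor (0.25 ± 0.07, adjusted p = 0.0298). Its adapter Tyrobp did not pass (0.22 ± 0.07, adjusted p = 0.0595), and the list call was lost with an estimated correlation (adjusted p = 0.340).

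Interferon response genes were higher in 36 of 37 cases with a median log2 difference of 0.31. In this list 9 were called, among them Trim30a (0.48), Ifi27l2a (0.70), Eif2ak2 (0.33) and Gbp2 (0.34), and 19 when adjusted over the list alone, and the list's adjusted p was 0.378 with an estimated correlation. All 21 myelin genes were higher, with a median of 0.27. Called members were Mag (0.38), a myelin glycoprotein gene, Ugt8a (0.31), Tspan2 and Ermn, and 12 passed when adjusted over the list alone (adjusted p of the list with an estimated correlation 0.474). Of antigen presentation genes, 15 of 18 were higher and 2 were called, including B2m (0.30), with an adjusted p of 0.635 under an estimated correlation. Among 22 reactive astrocyte genes, 4 were called higher, including Serpina3n, Gfap (0.35) and Osmr (0.33), and Cd44 was called lower (-0.48). The median over this list was 0.07 and its adjusted p 0.449 with an estimated correlation. The 10 X-linked and Y-linked genes were also all higher (median 0.10, with Kdm5d at 1.04, Xist at 0.79 and Ddx3y at 0.79, adjusted p of the list 0.317 with an estimated correlation). These values weigh both sexes equally, including males with Xist at most at 1.89 CPM and females with Ddx3y at most at 0.772 CPM. They are therefore not expression differences within the sex that expresses the gene.

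Large differences at single genes lay outside these lists. Eps8l1, an adapter of actin signalling on chromosome 7, was at 0.364 ± 0.211 CPM in APP/E3 and 5.24 ± 2.73 CPM in APP/E4. Higher in APP/E4 were also Fam205c on chromosome 4 (log2 difference 2.29 ± 0.36) and Tmc4 on chromosome 7 (1.29 ± 0.16). Ighg2c, an immunoglobulin heavy chain constant gene on chromosome 12, fell from 4.07 ± 1.07 CPM to 0.174 ± 0.292 CPM, and its close relatives can share its reads. Wdfy1 on chromosome 1 fell from 39.7 ± 16.2 to 15.9 ± 2.0 CPM, and Dmkn, Cyp2f2 and Rpl28 on chromosome 7, Vill on chromosome 9 and Sox2ot on chromosome 3 also fell (log2 differences -1.79 ± 0.27, -2.43 ± 0.68, -1.05 ± 0.13, -1.14 ± 0.31 and -0.93 ± 0.18). Rpl28 can share reads with its pseudogenes. Apoe (-0.04 ± 0.05), App (0.02 ± 0.04) and Prnp (-0.05) did not pass. With read class as a term, edgeR called 1306 genes, 1006 of them shared with the 1032. With read class and title style as terms it called 1711, voom called 1860, and in class 1 alone edgeR called 402, of which 332 were shared, and there the calls of Cyp2f2, Vill, Rn18s, Trem2, Ifi27l2a, Bst2, B2m and Mag ended. Among the calls named here, Cyp2f2 was lost without APP/E3 ND female 6 (adjusted p = 0.0515), Trem2 without APP/E3 ND male 1 or APP/E4 HFD male 3 (at most 0.0620), Osmr without APP/E4 HFD male 3 (0.0553) and Ugt8a without APP/E4 ND male 1 (0.0516), while Mag was lost without any of 6 libraries, Tspan2 without any of 16, Ermn without any of 34 and Cd44 without any of 36.

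**Figure D2:**
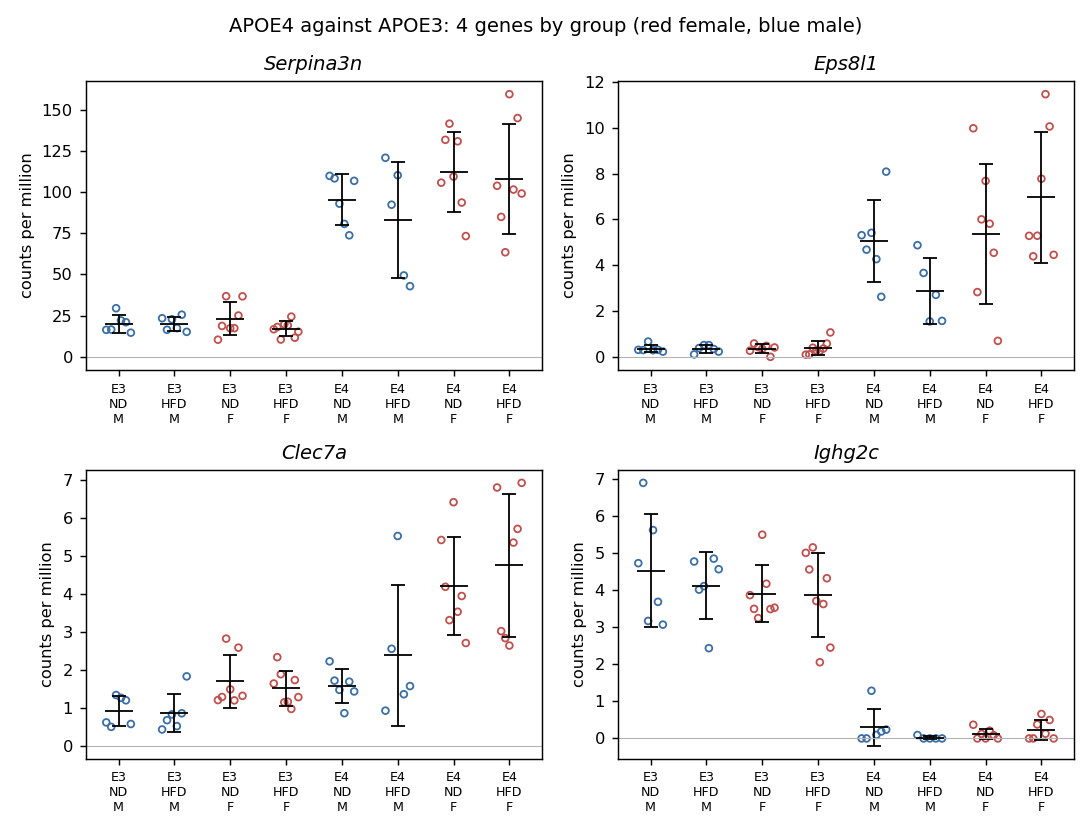
CPM of Serpina3n, Eps8l1, Clec7a and Ighg2c in each library (points) by the 8 groups of genotype, diet and sex, with the group mean and SD. Serpina3n and Eps8l1 lie higher in the APP/E4 groups, and Ighg2c lies near 0 there against a mean of 4.07 CPM in APP/E3. The mean of Clec7a is higher in APP/E4 than in APP/E3 of the same sex and diet. Its values in APP/E4 males overlap those in APP/E3 females, and APP/E4 females have the highest means.

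The comparison of females with males, averaged over genotype and diet, asked how sex shapes the same tissue. Microglial genes were higher in females. Tyrobp was at 23.7 ± 4.94 CPM in 29 females and 17.4 ± 4.50 CPM in 23 males (SD), and Trem2 at 21.5 ± 4.75 against 16.1 ± 3.43 CPM. Cst7 was at 5.001 ± 3.15 against 2.06 ± 2.07 CPM and the complement gene C1qa at 71.5 ± 11.9 against 57.0 ± 8.38 CPM. The interferon-induced genes Bst2 (5.90 ± 2.28 against 3.25 ± 1.01 CPM) and Oasl2 (9.70 ± 5.48 against 4.995 ± 1.60 CPM) and the astrocyte filament gene Gfap (256 ± 90.2 against 156.7 ± 39.04 CPM) rose as well. Within class 1 alone the differences had the same direction, with Tyrobp at 24.4 ± 5.27 CPM in 18 females and 18.5 ± 5.18 CPM in 15 males, Cst7 at 5.21 ± 3.12 against 2.49 ± 2.44, Bst2 at 6.90 ± 2.29 against 3.37 ± 1.12, Oasl2 at 11.4 ± 6.10 against 5.02 ± 1.62 and Gfap at 247 ± 54.5 against 157 ± 41.5 CPM. In edgeR on class 1 alone after refiltering, Tyrobp, Trem2 and Cst7 did not pass (adjusted p = 0.0685, 0.0581 and 0.0592). C1qa, Bst2, Oasl2 and Gfap were still called there (at most 0.0228).

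Without a class term edgeR called 671 genes, 442 higher and 229 lower in females. With read class as a term it called 199, of which 133 were among the 671, and within class 1 alone 126, of which 91 were among them. For female against male averaged over genotype and diet, 27 of 29 plaque-associated microglia genes were higher, with a median of 0.36, and 18 were called (22 when adjusted over the list alone). This was the single list of this comparison that camera called with an estimated correlation (adjusted p = 4.1e-04), and its adjusted p was 0.00176 with the class term and 0.00975 within class 1. Interferon genes were higher in 36 of 37 cases with a median of 0.45, and 25 were called (33 adjusted over the list alone), among them Ifi44 (0.90), Rtp4 (0.71) and Ifit3 (0.60). Their adjusted p with an estimated correlation was 0.107 without and 0.0241 with the class term. In the Tyrobp network 44 of 45 genes were higher and 12 were called, with adjusted p values of 0.193 and 0.0263 in the same 2 fits, and 19 were called adjusted over the list alone. Homeostatic microglia (18 of 20 higher, 6 called, including Fcrls), complement (14 of 18, 4 called, including C1qc) and antigen presentation genes (16 of 18, 6 called, including H2-K1 and H2-D1) gave adjusted p values of 0.193, 0.207 and 0.158 with an estimated correlation and 0.0241, 0.0263 and 0.0263 with the class term as well. The calls of these 5 lists under an estimated correlation were lost within class 1 alone (adjusted p at least 0.0665) and with class and title terms together (at least 0.118), where the plaque-associated list alone was called (0.00975 and 0.0463). Apoe (0.21 ± 0.05) and App (0.15 ± 0.04) were called higher in females, whereas Prnp was not called (adjusted p = 0.144).

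Ribosomal protein genes behaved differently. Of 66 genes of the cytosolic ribosome 54 were higher in females and 23 were called higher, led by Rps10 (9.47 ± 8.78 against 3.45 ± 1.29 CPM), Rpl37a (11.5 ± 8.98 against 4.72 ± 0.66 CPM), Rpl37 and Rpl13a (1.16 ± 0.21). Within class 1, Rps10 stood at 2.82 ± 0.50 CPM in females and 2.72 ± 0.85 CPM in males, and with the class term 2 of the 23 were still called. Reads of these genes can be shared with their pseudogenes. Tuba1c, Rpl37a, ND4L and Atp5o changed sign with the class term (-0.015, -0.0029, 0.11 and -0.040). Ttr, the choroid plexus transthyretin gene, was at 135 ± 464 CPM in females and 7.01 ± 8.47 CPM in males, and its SD was larger than its mean. It reached 2402 TMM-scaled CPM in APP/E3 HFD female 6, with the next highest library, APP/E4 HFD female 5, at 651. Of 13 choroid plexus genes 10 were higher and 3 called, with an adjusted p of 0.545 under an estimated correlation. All 19 striatal genes were lower (median -0.34, adjusted p 0.473), and 12 of 15 olfactory bulb genes were lower (median -0.17, adjusted p 0.545). These values carry no class term, and class 2, which is all female, was low in such markers. The striatal gene Drd2 had a median of 3.9 TMM-scaled CPM in class 2 and 28.4 in class 1, and the olfactory gene Omp 0.192 and 2.83. Sex and read class are therefore not separated in them.

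Fry, which does not compare a list with other genes, called 13 lists between the sexes, all also called by camera in the same direction. With an estimated correlation, the other lists called by camera in the sex comparison lost the call, and the adjusted p values below are from that test. Reactive astrocyte genes were higher in 19 of 22 cases (adjusted p = 0.234), with Gfap and the chemokine gene Cxcl10 called higher and the iron carrier gene Lcn2 called lower. Astrocyte identity genes were higher in 19 of 21 cases with 3 called (adjusted p = 0.219), endothelial genes in 23 of 23 with none called (0.234; 5 adjusted over the list alone), fatty acid oxidation genes in 22 of 26 with 2 called (0.212), oxidative phosphorylation genes in 47 of 56 with 5 called (0.486) and chaperone genes in 30 of 34 with 5 called (0.323). Transcription and chromatin regulators were lower in 35 of 50 cases with 4 called lower (0.557), and Alzheimer risk genes higher in 23 of 33 with 5 called higher and 1 lower (0.234). The X-linked and Y-linked check list had all 10 genes called, with 6 higher and 4 lower. Its median was 0.26 while camera gave it the direction down, because the Y-linked differences are larger (adjusted p 0.212 with an estimated correlation). The granulocyte genes S100a9, S100a8 and Ngp were called lower in females (-1.78, -1.70 and -2.26). S100a9 and Ngp were lost without APP/E4 HFD male 3, S100a9 also without APP/E3 ND male 1 or APP/E4 ND male 3 (adjusted p at most 0.204 for S100a9 and 0.0758 for Ngp), and S100a8 without any of 14 libraries.

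All females and 27 of the 33 class 1 animals have a sex letter in their titles, and males without one formed part of every male group. With read class and title style both as terms, edgeR called 32 genes between the sexes, of which 27 were among the 671, with title style alone 18 and with lettered males alone 14. For female against male averaged over genotype and diet, voom called 2112 with no such term. With class and title terms the plaque-associated microglia list kept an adjusted p of 0.0463 with an estimated correlation. Tyrobp then differed by 0.25 (adjusted p = 0.306) and Trem2 by 0.26 (0.298), whereas Ctsd (0.26), Fcrls (0.36), Gfap (0.68), Bst2 (0.96) and Oasl2 (1.12) were still called. With all libraries and no term, the count of 671 fell to 431 without APP/E4 HFD male 5 and rose to 1061 without APP/E4 ND male 6.

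**Figure D3:**
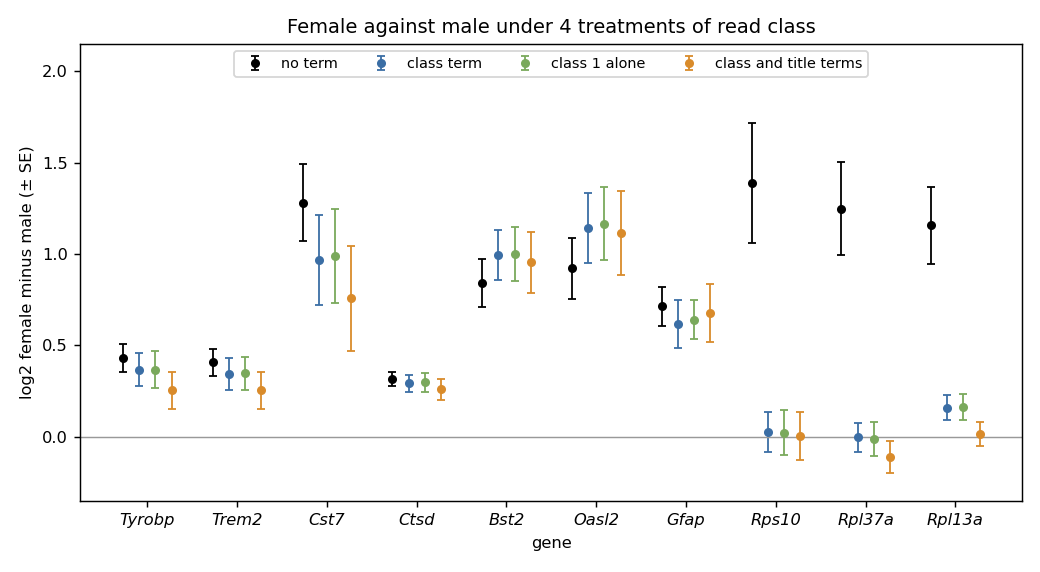
Log2 difference, female minus male, of 10 genes with its standard error (bars), from fits with no class term, with a class term, in class 1 alone and with class and title terms. Rps10 and Rpl37a fall from 1.39 and 1.249 to near 0 once read class is taken into account, while Bst2 (0.84 without and 0.996 with the class term) and Oasl2 (0.92 and 1.14) do not.

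The diet comparison asked what HFD changed in these mice. Averaged over genotype and sex, no gene was called by edgeR, while DESeq2 called 2 and voom 1, and 1398 genes had an unadjusted p under 0.05 (669 higher, 729 lower) where about 760 would be expected by chance. Leaving out APP/E4 ND male 5 gave 2 calls, and leaving out APP/E4 HFD female 1 or APP/E4 ND female 6 gave 1 each. The smallest p belonged to Meox1, a homeobox gene of mesoderm-derived cells (-0.93 ± 0.19), Btaf1, a regulator of TATA-binding protein (0.22 ± 0.05), Tipin (-0.25 ± 0.06), Mpg (-0.18 ± 0.04) and Borcs6 (-0.20 ± 0.05), none of which passed (adjusted p at least 0.111). By list, 34 of 37 interferon genes (median 0.14), 36 of 45 Tyrobp network genes (0.09), 29 of 33 immediate early genes (0.17) and 46 of 50 transcription and chromatin regulators (0.05) were higher on HFD. Lower were 53 of 56 oxidative phosphorylation genes (median -0.07) and 21 of 24 cholesterol synthesis genes (-0.10). Camera called these 6 lists and 8 others, and none held with an estimated correlation (adjusted p = 0.525 for each of these 6). Adjusted over the list alone, 7 oxidative phosphorylation genes were called lower and 5 transcription regulators higher, and none in the other 4.

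Plaque-associated microglia (21 of 29 higher, median 0.07), reactive astrocyte (16 of 22, 0.06), endothelium (17 of 23, 0.08), glucocorticoid response (21 of 26, 0.09), chaperone (27 of 34, 0.04) and cell migration genes (41 of 57, 0.04) were higher, each with an adjusted p of 0.525 under an estimated correlation. The 13 choroid plexus genes were all higher (median 0.71, adjusted p 0.525) and 18 of 19 striatal genes lower (-0.22, adjusted p 0.640). Circadian clock genes (13 of 18 higher, camera adjusted p 0.0511), lipid handling genes (14 of 33 higher, 0.837), oligodendrocyte precursor genes (10 of 15 higher, 0.481) and hippocampus and thalamus genes (8 of 20 higher, 0.537) were not called, nor were they in any of the other 11 contrasts.

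In APP/E4 females, HFD went with higher glial and vascular genes as groups, but no list held with an estimated correlation (smallest adjusted p 0.197), and choroid plexus and striatal genes moved in the same animals. Of the Tyrobp network 43 of 45 genes were higher (median log2 difference 0.23), among them the kinase genes Syk (0.41 ± 0.14) and Lyn (0.46 ± 0.16), the receptor Tlr7 (0.47 ± 0.17) and Csf1r (0.26 ± 0.10). The homeostatic microglia gene Tmem119 (0.35 ± 0.10) passed when adjusted over its list alone, as did the endothelial transporters Mfsd2a (0.39 ± 0.12) and Slc16a1 (0.26 ± 0.08). All 21 astrocyte identity genes (median 0.16) and all 23 endothelial genes (0.21) were higher. Cholesterol synthesis genes were lower in 22 of 24 cases (median -0.13), with Acat2 (-0.29 ± 0.09) and Sqle (-0.27 ± 0.09) among the 3 genes called lower when adjusted over the list alone. No single gene was called by edgeR, DESeq2 or voom, 1201 had an unadjusted p under 0.05 (730 higher, 471 lower), and the smallest p was that of the thiamine transporter gene Slc19a3, at 5.32 ± 0.67 CPM on HFD and 3.30 ± 0.46 CPM on ND (SD, n = 7 each, adjusted p = 0.166).

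Camera called 17 lists in APP/E4 females, and none held with an estimated correlation. The adjusted p was then 0.197 for the Tyrobp network, plaque-associated microglia (26 of 29 higher, median 0.18), homeostatic microglia (17 of 20, 0.17), complement (17 of 18, 0.21), astrocyte identity, endothelium, cholesterol synthesis and fatty acid oxidation (19 of 26, 0.11). It was 0.334 for interferon response (36 of 37, 0.20) and antigen presentation (17 of 18, 0.18), and 0.276 for reactive astrocytes (18 of 22, 0.21). Immediate early (27 of 33 higher), ribosome (51 of 66 higher), chaperone (21 of 34 higher) and oxidative phosphorylation genes (40 of 56 lower) had adjusted p values of at least 0.742, and the mean log2 difference of the immediate early genes went from 0.16 to 0.02 without APP/E4 ND female 5. Without APP/E4 ND female 2 those of ribosome and chaperone genes went from 0.08 to 0.03 and from 0.08 to 0.04. That of oxidative phosphorylation genes went from -0.03 to -0.0042 without APP/E4 HFD female 6. Tissue markers moved in the same animals: all 13 choroid plexus genes were higher (median 1.63, adjusted p 0.276) and all 19 striatal genes lower (-0.83, adjusted p 0.357). The fitted median of the 15 olfactory bulb genes was 1.17 without a camera call (adjusted p 0.961, camera direction down), and their mean log2 CPM was 5.61 in APP/E4 HFD female 4 and differed by 0.07 between diets (exact permutation p = 0.929). Without the libraries above 100 CPM of Ttr, 3 of which were APP/E4 HFD females, the medians were 0.21 for the Tyrobp network, 0.14 for astrocyte identity, 0.17 for endothelium, 0.06 for interferon response, 0.05 for reactive astrocytes and -1.21 for the olfactory bulb, where the sign turned.

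The mean log2 CPM of the Tyrobp network was 3.37 ± 0.17 on HFD and 3.141 ± 0.20 on ND in APP/E4 females (SD, n = 7 each). The difference of 0.23 had an exact permutation p of 0.0437, or 0.175 adjusted over the 4 combinations of genotype and sex, and in class 1 alone it was 0.19 (exact permutation p = 0.127). The same test in these females gave 0.00699 for endothelium (0.0280 adjusted over the 4 combinations) and 0.0169 for astrocyte identity (0.0676), and the other lists under 0.05 after this adjustment were transcription regulators in APP/E3 males (0.0108, adjusted 0.0433) and blood genes in APP/E3 females (0.0124, adjusted 0.0497). These p values were not adjusted over the lists. It was 0.13 in APP/E4 males (exact permutation p = 0.327), 0.03 in APP/E3 females (0.8002) and -0.07 in APP/E3 males (0.204). Without APP/E4 HFD male 3 the difference in APP/E4 males was 0.0094, and that library was also in class 1, where the difference was 0.24 with 3 HFD and 4 ND males. The difference in APP/E3 females was below 0 without APP/E3 ND female 2 or 4 or APP/E3 HFD female 5 (-0.015 at the lowest, without the last), and 0.095 at the highest. The list was prompted by the series description and is not independent evidence.

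**Figure D4:**
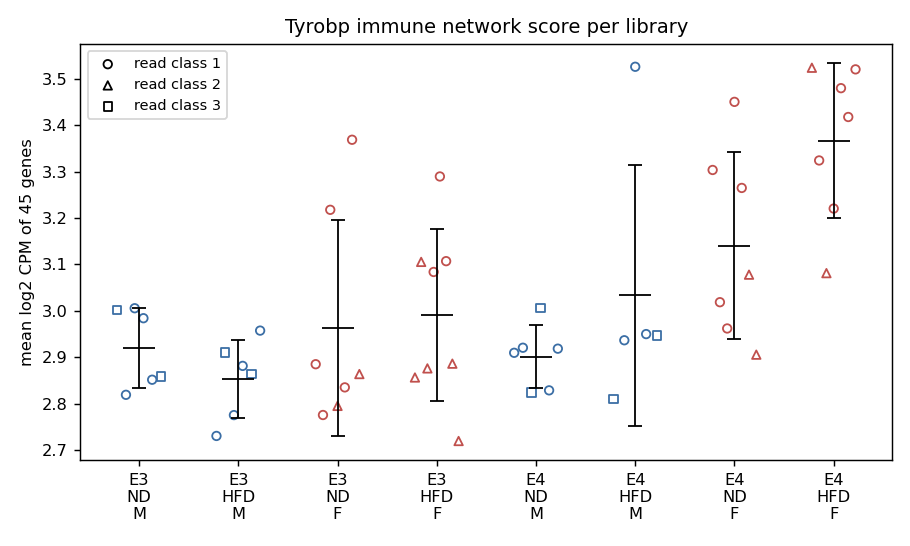
Mean log2 CPM of the 45 measured Tyrobp network genes in each library (points, marked by read class) by group, with the group mean and SD. The mean is highest in APP/E4 HFD females at 3.37, against 3.141 in APP/E4 ND females, and APP/E4 HFD male 3 stands apart from its group at 3.53.

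In APP/E4 males, HFD went with higher interferon genes (32 of 37, median 0.24), Tyrobp network genes (36 of 45, 0.15) and excitatory neuron genes (32 of 34, 0.12), each with an adjusted p of 0.624 under an estimated correlation. The Tyrobp network difference rested on APP/E4 HFD male 3, without which the mean log2 difference went from 0.13 to 0.0094, and those of plaque-associated microglia, endothelium and striatum went from 0.16 to 0.05, from 0.11 to 0.03 and from -0.90 to -0.35. Cst7 (1.37 ± 0.45), Ccl6 (0.65 ± 0.23), Itgax (0.96 ± 0.35) and Sp100 (0.71 ± 0.23) were the leading members and did not pass over all genes (adjusted p = 0.995 each). The neutrophil genes S100a8 (3.17 ± 0.96), S100a9 (3.09 ± 0.93) and Ngp (2.77 ± 0.99) passed when adjusted over the blood list alone, and Lcn2 (2.48 ± 0.69) over the glucocorticoid list alone. In this group APP/E4 HFD male 3 had a mean log2 CPM of blood genes of 3.57, against at most 0.233 in the other 4. Without that library the mean log2 difference of blood genes between diets went from 0.69 to -0.06. EdgeR called 0 genes, voom 0 and DESeq2 1, with 555 at an unadjusted p under 0.05, and 1 gene was called by edgeR without APP/E4 HFD male 1. Slc9b2 (0.95 ± 0.22), Tusc1 (-0.88 ± 0.23), Metrn (-0.46 ± 0.14) and Kiz (-0.37 ± 0.11) had the smallest p with Lcn2 (adjusted p at least 0.863).

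Camera called 15 lists in APP/E4 males, with no call under an estimated correlation. The adjusted p was then 0.624 for the 3 lists above and for plaque-associated microglia (20 of 29 higher), complement (13 of 18), immediate early (28 of 33), glucocorticoid response (17 of 26) and transcription regulators (41 of 50), and for the lower lists of inhibitory neurons (14 of 22, median -0.15), oxidative phosphorylation (53 of 56, -0.11) and striatum (19 of 19, -0.55). It was at least 0.628 for endothelium (17 of 23 higher), chaperones (26 of 34 higher), myelin (20 of 21 lower, -0.13) and olfactory bulb (15 of 15 lower, -1.20). Without APP/E4 ND male 6 the mean log2 differences of transcription regulators and oxidative phosphorylation genes went from 0.07 to 0.01 and from -0.08 to -0.02, and without APP/E4 ND male 3 that of olfactory bulb genes from -0.52 to -0.13. That of excitatory neuron genes went from 0.15 to 0.095 without APP/E4 ND male 6. Those of chaperones and myelin genes went from 0.07 to 0.04 (APP/E4 ND male 4) and from -0.13 to -0.08 (APP/E4 ND male 1). Cell migration genes, a theme named for this group in the series description, were higher in 27 of 57 cases (median -0.02, camera adjusted p 0.859).

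In APP/E3 females on HFD, hemoglobin transcripts fell. Hba-a1 was at 1.21 ± 0.50 CPM on HFD (SD, n = 8) and 24.0 ± 49.1 CPM on ND (SD, n = 7), Hbb-bs at 0.310 ± 0.169 against 7.32 ± 15.3 CPM and Hbb-b1 at 0.650 ± 0.317 against 11.4 ± 23.8 CPM. With Rn18s, the 18S ribosomal RNA, at 1318 ± 469 against 8501 ± 16040 CPM, these were the 4 genes called by edgeR (each adjusted p = 0.0431). DESeq2 called 8 genes and voom 0, and 713 genes had an unadjusted p under 0.05. All 4 calls were lost when single libraries of either diet were left out, and the highest values lay in single ND libraries. Hbb-bs reached 41.7 CPM in APP/E3 ND female 5 and Rn18s 44260 CPM in APP/E3 ND female 1, no gene was called without both, and the count was 0 without APP/E3 ND female 1 or any 1 of the 8 HFD libraries, 7 without APP/E3 ND female 3 or 6 and 8 without APP/E3 ND female 7. The 3 hemoglobin calls also ended without APP/E3 ND female 5, where Hbb-bs differed by -2.31.

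In the same females camera called 9 lists, all lost with an estimated correlation, and class 2 held more of the HFD females. With the class term 13 lists were called, of which 5 were among the 9 in the same direction, and in class 1 alone 23, of which 6 were. The myelin and immediate early lists were called in the opposite direction in class 1 alone. All 8 blood genes were lower, 5 of them when adjusted over the list alone (adjusted p 0.792), and all 13 choroid plexus genes were higher (median 1.41, adjusted p 0.993), 7 of them when adjusted over the list alone, led by Ttr (4.52 ± 1.19) and F5 (2.30 ± 0.60). The choroid plexus score of APP/E3 HFD female 6 was 5.40, against at most 1.42 in the other 7. Cholesterol synthesis genes were lower in 21 of 24 cases (median -0.11, adjusted p 0.616), with Idi1 (-0.53 ± 0.16) called over the list alone, and transcription regulators higher in 42 of 50 (0.09, adjusted p 0.616), with Kmt2a (0.44 ± 0.11) called over the list alone. Myelin genes (21 of 21) and mural and fibroblast genes (20 of 25) were lower, and immediate early (23 of 33), glucocorticoid response (19 of 26) and ribosome genes (49 of 66) higher, with adjusted p values of at least 0.981. Leaving out single libraries took the mean log2 difference of myelin genes from -0.14 to 0.0039 (APP/E3 ND female 4), of immediate early genes from 0.13 to 0.02 (APP/E3 ND female 7), of mural and fibroblast genes from -0.26 to -0.06 (APP/E3 HFD female 1) and of choroid plexus genes from 0.64 to 0.10 (APP/E3 HFD female 6).

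In APP/E3 males on HFD, 63 of 66 ribosomal protein genes (median -0.24), 49 of 56 oxidative phosphorylation genes (-0.18) and 19 of 21 astrocyte identity genes (-0.13) were lower. Ntsr2 (-0.36 ± 0.09) and Aldoc (-0.24 ± 0.08) passed when adjusted over the astrocyte list alone, and over their own lists alone 3 ribosomal, 7 oxidative phosphorylation and 2 astrocyte genes were called lower. Immediate early genes (29 of 33, 0.27), myelin genes (19 of 21, 0.21), transcription regulators (41 of 50, 0.12) and all 19 striatal genes (0.38) were higher. Camera called these 7 lists, and each had an adjusted p of 0.941 with an estimated correlation. Without APP/E3 ND male 3 the mean log2 differences of astrocyte identity and myelin genes went from -0.11 to -0.07 and from 0.21 to 0.13. That of oxidative phosphorylation genes went from -0.15 to -0.09 without APP/E3 HFD male 4, and that of striatal genes from 0.83 to 0.44 without APP/E3 ND male 4. Dcun1d3, a cullin neddylation gene, was at 29.2 ± 1.69 CPM on HFD and 22.7 ± 1.81 CPM on ND (SD, n = 6 each, adjusted p = 0.0748). Umodl1 (-4.38 ± 0.89), Bpifb4 (-7.61 ± 1.61), Cnga2 (-3.95 ± 0.89) and Sec14l3 (-3.54 ± 0.81) followed, and Umodl1 reached 72.8 CPM in 1 ND library against a group mean of 13.8 ± 29.1. The olfactory marker gene Omp was at 277.5 TMM-scaled CPM in APP/E3 ND male 3 and at most 52.06 in the other 5 ND males. EdgeR called 0 genes, voom 3 and DESeq2 6, with 2064 at an unadjusted p under 0.05 (943 higher, 1121 lower). With 2 surrogate variables edgeR called 18. It called 9 genes without APP/E3 ND male 1, 7 without APP/E3 ND male 4, 3 without APP/E3 ND male 2, 2 without APP/E3 HFD male 4 and 1 without APP/E3 ND male 6.

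The interactions asked whether the response to HFD differed between genotypes or sexes. Averaged over sex, the response of 42 of 45 Tyrobp network genes (median 0.23), 22 of 23 endothelial genes (0.15) and 20 of 21 astrocyte identity genes (0.13) was more positive in APP/E4 than in APP/E3, and that of 38 of 50 transcription regulators (-0.09) and 19 of 19 striatal genes (-0.99) more negative. Camera called 11 lists, among them these 5 with an adjusted p of 0.636 under an estimated correlation. EdgeR, DESeq2 and voom called 0 genes, with 1515 at an unadjusted p under 0.05. Prr13 (0.38 ± 0.09), Serhl (0.65 ± 0.16), Ntsr2 (0.35 ± 0.09) and Pik3cd (0.29 ± 0.07) had the smallest p among named genes (adjusted p at least 0.451). Within class 1, edgeR called 12 genes. In females, Fam49a (-0.43 ± 0.11), Tmco6 (0.48 ± 0.13), Rn18s (2.89 ± 0.76) and Sema6c (0.53 ± 0.14), and in males Slc9b2 (1.27 ± 0.30), Prr13 (0.51 ± 0.14), Ehmt1 (-0.37 ± 0.10) and Etnk2 (1.36 ± 0.38), led without a call by any of the 3 tools. The counts at an unadjusted p under 0.05 were 922 and 702, and camera called 14 and 9 lists, none with an estimated correlation (Tyrobp network adjusted p 0.634 and 0.831). The 14 calls in females fell to 7 with the class term, 6 of them shared, and to 7 in class 1 alone, 2 of them shared.

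Between the sexes, the response to HFD of 57 of 66 ribosomal protein genes (median 0.27) and 21 of 21 astrocyte identity genes (0.14) was more positive in females, and 14 ribosomal genes passed when adjusted over the list alone. Both lists had an adjusted p of 0.494 with an estimated correlation, and class 2 held 5 of 8 HFD against 2 of 7 ND females in APP/E3. Srek1ip1 (0.37 ± 0.08), D2Wsu81e (0.27 ± 0.06), Unc119 (0.44 ± 0.11) and Arl5b (-0.69 ± 0.16) did not pass (adjusted p at least 0.382). EdgeR and DESeq2 called 0 genes and voom 2, with 1191 at an unadjusted p under 0.05, and camera called 14 lists. Within APP/E4, Slc19a3 (0.87 ± 0.21) had the smallest p (adjusted p = 0.997), followed by Srek1ip1 (0.47 ± 0.12), Arid3c, D17H6S53E and D2Wsu81e. EdgeR and voom called 0 genes and DESeq2 1, with 585 at an unadjusted p under 0.05. Of the 10 lists camera called there, excitatory neuron (30 of 34 lower, median -0.16) and cholesterol synthesis genes (19 of 24 lower, -0.20) responded more negatively in females, with an adjusted p of 0.531 under an estimated correlation, and the Tyrobp network had an adjusted p of 0.801.

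The authors' deposited table gives 1207 genes an unadjusted p under 0.05 for diet, of which 1206 are in the shorter table, with 598 positive and 608 negative coefficients. Adjusted here by Benjamini-Hochberg, the smallest p in the authors' deposited table was 0.464. Of the 1185 of these genes that were also tested here, 1032 had an unadjusted p under 0.05 in the averaged diet contrast of edgeR. Across genes, which are not independent replicates, the coefficients in the authors' deposited table ran opposite to the log2 differences of HFD minus ND (Spearman's rho = -0.945), and none of the 1032 shared genes had the same sign, so the deposited coefficients read as ND minus HFD.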

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

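The regrouping of all libraries was planned before the data were examined, and the regrouping within class 1 and the tests of read class, of title style together with read class, of neighbouring genes, of reactive astrocytes and of tissue scores were chosen after the results were seen.

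Genes higher in females included 23 ribosomal protein genes and 54 genes of the plaque-associated microglia, Tyrobp network and interferon lists. The real division was the 1 of 100 divisions of the libraries to reach its count. This held over all libraries (671 calls, highest other 1) and within class 1 (126 calls, highest other 6). The counts take all genes, including the X-linked and Y-linked genes that the real division was bound to call. They were not made for the 23 or the 54 genes alone, so chance was not tested for these. Over all libraries the divisions also did not keep read class, which differs between the sexes. Read class accounts for most of the ribosomal part: with the class term 2 of the 23 genes were still called and their median log2 difference went from 0.44 to 0.08. Read class is argued against for the microglial and interferon part, whose median with the class term was 107.7% of its value without. With that term 32 of the 54 genes were still called. In class 1 alone after refiltering the median was 104.8% of its value, with 52 genes measured and 19 still called. These included 6 of 18 plaque-associated genes and 1 of 12 Tyrobp network genes. Title style, which differs only among males, is argued against as its whole cause, since the median with both terms was 95.04% of its value (0.43 without and 0.41 with the terms), yet the median standard error rose from 0.101 to 0.144 and the calls fell from 54 to 7, while the plaque-associated genes among them went to 76.55% of their median (64.14% with the title term alone, 70.96% against the males with a sex letter), so larger errors and in part smaller differences ended these calls. Sex itself stays open, and title style stays open for part of the plaque-associated difference: against the males with a sex letter alone the median of all 54 was 0.37, with 54 of 54 genes higher and 0 called.

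The genes called between APP/E4 and APP/E3 clustered along chromosomes, and the 1032 calls were reached by 1 of 100 divisions of the libraries, the real one (highest other 3), so chance can be excluded for their number. Neighbouring genes were both called in 110 pairs, against a median of 72 and at most 107 in 10000 random placements, and in 95 pairs without chromosome 7, which carries Apoe, against at most 92. Linked chromosome segments that differ between the genotype lines may contribute, but calls of the sex comparison, made within the lines, also neighboured each other (45 pairs, random median 28, as many in 11 of 10000 placements), so segments cannot be told apart from the ordinary clustering of related genes. A general rise of reactive astrocyte genes as the source of the higher Serpina3n is argued against. The other 21 members of that list had a median log2 difference of 0.067 ± 0.084 (SE over members), against 2.31 for Serpina3n. Of these members 3 were called higher and 1 lower. The values do not show which cells carried the higher Serpina3n, and a linked segment at its own locus was not tested. An effect of the APOE allele itself stays open and was not tested apart from the lines.

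In APP/E4 females 17 lists were called on HFD (8 with the tissue scores as covariates), with glial and vascular lists higher, but 9 of 100 divisions gave as many lists (highest other 22) and 25 of 100 as many genes at an unadjusted p under 0.05 (1201, highest other 2624), so chance cannot be excluded. Read class is argued against as the cause by the design, since class 2 held 2 of 7 ND and 2 of 7 HFD females of APP/E4. In class 1 alone the lowest of the medians of the Tyrobp network, astrocyte identity and endothelium lists was still 79.36% of its value. With this balance that value is no separate evidence. Choroid plexus, striatal and olfactory tissue in the dissected piece cannot be told apart from diet: with the tissue scores as covariates the medians went to 80.3% for the Tyrobp network, 61.9% for endothelium, 45.07% for astrocyte identity, 101% for homeostatic microglia, 56.99% for plaque-associated microglia, 44.88% for complement, 38.73% for antigen presentation, 28.01% for interferon response, 12.57% for reactive astrocytes and -27.05% for mural cells, some above and some below the level at which tissue would have been excluded. Diet as a cause stays open as well.

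Single libraries stood apart from their groups in 7 of 52 sets of values tested by the gap to the next library. A rate of about 1 in 20 by chance holds for normally distributed values, which total counts and CPM need not be. Rn18s and Hbb-bs were tested only in APP/E3 females, where they had been called. The total count of APP/E3 ND male 5 was 39.39 M, and the next highest of its group 13.13 M. The mean log2 CPM of the Tyrobp network in APP/E4 HFD male 3 was 3.526, and the next highest 2.95. The choroid plexus score of APP/E3 HFD female 6 was 5.398, and the next highest 1.419. The blood score was 2.918 in APP/E3 ND male 1, with the next highest at 0.196, and 3.57 in APP/E4 HFD male 3, with the next highest at 0.233. Rn18s was at 45970 TMM-scaled CPM in APP/E3 ND female 1, with the next highest at 9181, and Hbb-bs at 41.73 in APP/E3 ND female 5, with the next highest at 5.67.

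The effect of genotype on Hccs, an X-linked gene for a mitochondrial heme-attaching enzyme, differed between the sexes: the interaction was -0.9321 on the log2 scale (adjusted p = 5.8e-12 by edgeR with the class term), and it was the single gene called for it.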

How the results depend on the processing

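Most settings were chosen before the data were examined, and the read class, title with class, tissue score and doubted-library fits were added afterwards. Of 4582 values of named genes under other settings, 3841 counted as the same. These were called in the same direction in both fits, or called in neither and moved by less than 1 SE, whatever their sign. Another 609 no longer passed, 27 newly passed and 28 changed sign with a call in at least 1 of the 2 fits. The other 77 were called in neither fit and moved by at least 1 SE. Depth limits genes near 3 counts, which correspond to up to 0.561 CPM in the shallowest library. No paired analysis was possible because replicate numbers only follow the deposit order. Where no cause is given, the cause was not tested.

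For the averaged diet effect (0 calls) DESeq2 gave 2, voom 1 and leaving out single libraries 0 to 2. In APP/E3 males (0) no filter gave 4, DESeq2 6, voom 3, 2 surrogate variables 18, tissue scores 1 and single libraries left out 0 to 9. In APP/E3 females (4) DESeq2 gave 8, and voom, title style, 2 surrogate variables, read class, class 1 alone, class and title, tissue scores, no libraries above 100 CPM of Ttr, neither doubted library and the contrast's own libraries each gave 0, with 0 to 8 for single libraries left out. In APP/E4 males (0) DESeq2 gave 1 and single libraries left out 0 to 1. Class 1 alone gave 12 for the diet by genotype interaction (0), voom 2 and class with title 1 for the diet by sex interaction (0), and DESeq2 1 for the latter within APP/E4 (0). Leaving out single libraries gave 0 to 0 in APP/E4 females and in all 5 interactions.

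For APP/E4 against APP/E3 (1032) voom gave 1860, class with title 1711 and class 1 alone 405 after refiltering, where 33 libraries remain, and single libraries left out 792 to 1342. For female against male averaged over genotype and diet (671) voom gave 2112, title style 18, males with a sex letter alone 14, the class term 199, class 1 alone 129 after refiltering, class with title 32, tissue scores 291 and single libraries left out 431 to 1061. With title style or fewer males the errors grow. The voom fit differs from edgeR in its method and in weighting libraries by quality, and neither was tested as the reason for its counts. Over all contrasts there were 146 list calls at the preset correlation, 1 with an estimated correlation and 20 with fry. Of those with fry, 13 were for female against male and 7 for APP/E4 against APP/E3, of which camera also called 6 in the same direction. The Tyrobp network score difference in APP/E3 females was -0.015 to 0.095 with single libraries left out.

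All 28 sign changes that involved a call were in female against male. With class term, class 1 alone and class with title in turn, AA474408 gave -0.24, -0.20 and -0.23, Rpl37a -0.0029, -0.012 and -0.11, Tuba1c -0.015, -0.047 and -0.27, Atp5o -0.040, -0.041 and -0.13, and E030024N20Rik 0.17, 0.22 and 0.071. ND4L gave 0.11 and 0.12 in the first 2 of these. With class and title, Rpl37 gave -0.035, Ndufs6 -0.040, Uqcrh -0.057, Rps21 -0.050, Rps26 -0.012, Hspe1 -0.074, Crebbp 0.066 and Arid1b 0.045. Med1 gave 0.013 with title style, 0.0047 with lettered males alone and 0.020 with class and title.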

Other observations

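Further differences were seen in comparisons chosen after the data were examined. Among males, the Y-linked genes were higher in APP/E4 than in APP/E3, with log2 differences in edgeR with the class term of 1.248 ± 0.08 for Eif2s3y, 1.07 ± 0.09 for Ddx3y, 1.03 ± 0.09 for Kdm5d and 1.07 ± 0.11 for Uty (adjusted p at most 6.0e-09). Hccs on the X chromosome was higher by a like amount in the same males (1.05 ± 0.06). Among females, 22 of 25 genes of mural cells and meningeal fibroblasts were lower in APP/E4 than in APP/E3, with a median of -0.44 and 5 genes called lower (camera adjusted p = 0.0023, or 0.928 with an estimated correlation). With the class term 1061 genes were called between the genotypes in females and 188 in males, but the difference between these effects was called for 1 gene, Hccs.

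Called genotype genes were dense in a few stretches of the chromosomes. Within windows of 20 tested neighbours, 9 were called between Dcaf12 and Fam205c on chromosome 4, 9 between Tmc4 and Ptprh on chromosome 7, a stretch that includes Eps8l1, and 9 between Taf7 and Pcdhga12 on chromosome 18, where protocadherin genes share exons and reads. On chromosome 3 the window from Fxr1 to Bbs12 held 8 called genes with Sox2ot among them, and on chromosome 12 the window from Jag2 to Ptprn2 held 8, with the immunoglobulin genes Ighg2c and Ighm. By whole chromosome, the share of called genes was highest on chromosome 12 (63 of 553, 11.39%), followed by chromosome 7 (104 of 1143, 9.10%). Of the 100 genes nearest to Apoe, 13 were called, and the share over windows of 40 to 363 genes was 9.5% to 15%, where 1032 of 15195 were called in all. A hypothesis is that segments of another strain background, carried along in 1 of the lines, may set some of these differences. Its test, the 95 neighbouring pairs without chromosome 7, left it open.

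Most diet results were matched by regrouped libraries. The count of genes with an unadjusted p under 0.05 was reached by 7 of 100 divisions for the averaged diet effect (1398, highest other 1952), 42 for APP/E4 males (555, highest other 2191), 9 for the diet by genotype interaction (1515, highest other 2537), 39 for this interaction in females (922, highest other 3848), 32 in males (702, highest other 2028), 16 for the diet by sex interaction (1191, highest other 2402) and 58 for it within APP/E4 (585, highest other 2711), so chance cannot be excluded for these. The 4 calls in APP/E3 females were reached by 13 divisions (highest other 739). In APP/E3 males the real count of 2064 was reached by 1 division, the real one (highest other 2016). The count went from 865 without APP/E3 ND male 2 to 2448 without APP/E3 ND male 5, and no gene passed the adjusted threshold. It was the single diet contrast of those tested whose real division ranked first, so chance cannot be firmly excluded for that count. Divisions that called 739 genes in APP/E3 females, 1397 for the interaction with genotype in females and 365 for the interaction with sex in APP/E4 point to a structure of the samples.

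Regrouped libraries also gave many called lists at the preset correlation, with medians between 8 and 13. As many lists as the real division were called in 23 of 100 divisions for the averaged diet effect (14 lists, highest other 21), 71 for APP/E3 males (7, highest other 17), 72 for APP/E3 females (9, highest other 23), 14 for APP/E4 males (15, highest other 18), 34 for the diet by genotype interaction (11, highest other 21), 31 for it in females (14, highest other 24), 61 in males (9, highest other 19), 22 for the diet by sex interaction (14, highest other 20), 63 for it in APP/E4 (10, highest other 20) and 82 for the genotype comparison (7, highest other 23). For female against male 4 of 100 divisions called as many (19, highest other 21), and within class 1 the real division called 23 (highest other 24, median 13). The 19 include the X-linked and Y-linked check list, the divisions did not keep read class, and this is 1 of several such counts. Chance therefore cannot be firmly excluded for female against male, nor be excluded for the others.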
